A study of Mus musculus with 12 samples.

How the data were processed

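RNA was measured in brown adipose tissue (BAT, the heat-producing fat) of mice aged 8 to 10 weeks, with 12 libraries in 4 groups of 3. Per the labels, control animals carried 2 floxed Ebf2 alleles without Adipoq-Cre, and mutant animals carried the same alleles with Adipoq-Cre, a recombinase expressed in adipocytes. Animals stayed at room temperature or spent 1 week in the cold at 4 degrees, per the labels. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples, which may be technical. Ebf2 encodes a transcription factor of brown fat.

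The deposited table holds raw gene counts, 1 column per library, made by the authors with STAR and featureCounts on mouse build mm9, per the submitters' processing notes. Per the labels' protocols, total RNA was extracted with TRIzol and columns and made into libraries with a NEBNext Ultra RNA kit. Tool versions, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Members of near-identical gene families, such as Hspa1a and Hspa1b, the Cryg genes, the Serpina1 genes and the Acot genes, may therefore share reads, and overlapping or antisense genes cannot be separated. No coordinates are given, because the reference used for transcript lengths is another build (GRCm38, GENCODE M21).

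The table has 24197 genes, and library totals ran from 25835650 to 37927038 counts. At these depths 3 counts correspond to between 0.0764 and 0.114 CPM, the count scaled to a fixed library total, which was used as the floor of detection. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The chi-square per degree of freedom between replicates of a group ran from 40.7 to 249, so no pair was 1 library deposited again.

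Counts were tested with edgeR 4.0.16 in R 4.3.3. After filterByExpr (minimum count 10, minimum total 15), 15265 genes were tested. TMM normalization, robust dispersion estimation and the quasi-likelihood F-test (robust, legacy mode) were applied to all 12 libraries with 1 coefficient per group. The 5 contrasts were mutant against control at each temperature, cold against room temperature in each genotype, and their interaction. P-values are two-sided and adjusted by Benjamini-Hochberg, and a gene is called below 0.05. Standard errors (SE) are those implied by the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

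Gene lists numbering 36 were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. These list p-values were adjusted over all 180 tests. Camera with an estimated correlation called 0 of the 180 (against 70 with the preset), and its adjusted p, or the smallest over a group of lists, is given for lists called with the preset. At an unadjusted p under 0.05 the estimated version held 16 of the 180, and fry, which asks only whether a list moves on balance one way, called 28 of the 180. Beside the count of members called over all genes stands the count adjusted over the list alone.

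The lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names 14 genes always. For each comparison of 2 groups it adds the 8 called genes with the largest fold change in each direction, among those with mean CPM of at least 1 and no overlap between the groups, leaving out unnamed gene models. It also adds up to 2 called members of each list per direction, or the 2 most abundant members where none is called, and for the interaction the 5 genes per sign with the smallest p. Chance gives non-overlap for 10% of genes with 3 against 3. The epithelial genes Csn3, Krt8, Krt18, Krt19 and Epcam, and the room temperature values of Cryaa, were added after their values were seen. The rule was also extended then. Genes next in rank were added where lens genes took a top 8 place, or a top 5 place among positive interaction genes. They count among the named genes. Results for 2 genes that the rule names are not reported here.

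Replicate numbers are shared between groups, so the correlation of same-numbered deviations from the group means was checked. The outcome depended on the log scale. On log2 CPM with a prior count of 1, all 3 correlations passed 0.1 at room temperature (0.165, 0.719 and 0.488) and in controls across temperature (0.142, 0.647 and 0.456). On log2 of CPM plus 1, they did so only in mutants across temperature (0.264, 0.186 and 0.62). The second scale was tried first and the first was the one then used, so pairing is treated as unsettled and blocked counts are given for every comparison. No record ties a number to a shared litter or day.

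Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, other filters, only the groups compared, a non-robust fit, a replicate block and leaving out each library. After the data were seen, a muscle covariate, removal of each library's transcript-length trend (99.1% of tested genes had a length) and leaving out 4 muscle-rich libraries (over 0.9% of counts in the muscle list) were added. On simulated counts for 15265 genes with 100 genes changed 4-fold, the room temperature genotype test recovered 70% of them and the interaction 44%. For 100 genes changed 2-fold the values were 25% and 5%.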

Results

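The series compared gene expression in BAT between control mice and mice labelled as carrying an adipocyte deletion of Ebf2, at room temperature and after 1 week at 4 degrees. Each of the 4 groups held 3 libraries with between 25835650 and 37927038 counts. The question named by the labels was how control and Ebf2 mutant BAT differ in each temperature.

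Ebf2, the targeted gene, was not lower in the libraries labelled mutant at room temperature. Its level was 49.8 ± 13.9 CPM (SD, n = 3) there and 47.8 ± 16.1 CPM in controls, a log2 fold change of 0.06 ± 0.25 (SE, adjusted p = 0.931). The 3 mutant values were 65.2, 45.7 and 38.3 CPM, against 47.4, 64.1 and 32 CPM in controls. In the cold Ebf2 was 25.8 ± 3.73 CPM in mutants and 45.4 ± 6.04 CPM in controls, with mutant values of 28.7, 21.6 and 27 CPM and control values of 52.3, 42.2 and 41.6 CPM. That difference, -0.82 ± 0.25 on the log2 scale, had an adjusted p of 0.153 and was not called. The count covers the whole gene, so it may hold reads from exons that remain after recombination and from cells without Cre. Since the room temperature level does not bear out the label, mutant and control stand for libraries labelled so, and every direction given for genotype rests on those labels. Ebf1 and Ebf3 had log2 fold changes of 0.23 and 0.32 at room temperature and 0.12 and -0.05 in the cold, with no adjusted p under 0.212.

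**Figure D1:**
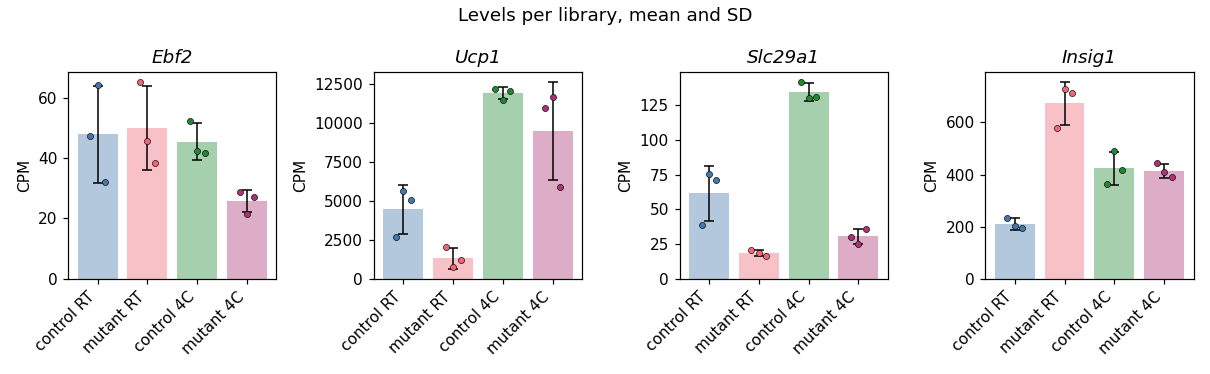
CPM of Ebf2, Ucp1, Slc29a1 and Insig1 in each of the 12 libraries (points), with the group mean (bar) and SD (line), against group on the horizontal axis. In the cold, Slc29a1 lies between 25.3 and 35.9 CPM in libraries labelled mutant and between 130 and 142 CPM in controls.

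At room temperature, members of the cholesterol synthesis and lipogenesis lists were called higher in libraries labelled mutant, and the respiratory chain was lower as lists, with few members called. No list kept its call with an estimated correlation. Ucp1, the uncoupling protein of brown fat, was 1308 ± 659 CPM (SD, n = 3) in mutants and 4454 ± 1557 CPM in controls (log2 fold change -1.77 ± 0.39 SE, adjusted p = 0.0199). In total 952 of 15265 genes were called, 598 higher and 354 lower in mutants. The count was 395 without control room temperature library 3, 460 without mutant library 2 and 497 without mutant library 3. Leaving out the 4 libraries richest in muscle transcripts, which leaves 1 control library at room temperature, gave far fewer calls. Most of those were lower in mutants, unlike in the main fit.

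Enzymes of cholesterol synthesis rose: 13 of 22 measured members were called higher, 0 lower, and 15 were higher adjusted over the list alone (camera adjusted p = 9.63e-14, adjusted p = 0.234 with an estimated correlation). Insig1, a sterol-responsive regulator of the pathway, rose from 209 ± 22 to 674 ± 82.5 CPM (SD, n = 3), and the sterol enzyme Nsdhl by 1.76 ± 0.20 on the log2 scale (SE). Lipogenic genes rose in the same comparison, with 14 of 22 called higher and 18 adjusted over the list alone (adjusted p = 7.73e-14, adjusted p = 0.318 with an estimated correlation). Among them Slc25a1, the mitochondrial citrate carrier, rose by 1.91 ± 0.24. General adipocyte genes had 9 of 24 called higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 2.37e-09, and adjusted p = 0.268 with an estimated correlation), including Agpat2 at 1.05 ± 0.18 and Cebpa at 1.24 ± 0.22. White-fat-enriched genes had 5 of 16 called higher and 9 adjusted over the list alone (adjusted p = 1.23e-06, adjusted p = 0.405 with an estimated correlation), with Retn, which encodes resistin, at 699 ± 33.5 CPM against 106 ± 43.8 CPM.

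Peroxisomal fatty acid oxidation had 7 of 20 members called higher and 8 adjusted over the list alone (adjusted p = 7.41e-05, adjusted p = 0.405 with an estimated correlation). Lipolysis and lipid uptake genes had 8 of 18 higher and 3 lower, 11 and 3 adjusted over the list alone (adjusted p = 0.00109, adjusted p = 0.234 with an estimated correlation), with the fatty acid binding protein gene Fabp5 at 2.34 ± 0.43 (SE; adjusted p = 0.0519 without control library 3). Fibroblast and preadipocyte genes had 2 of 20 higher (2 adjusted over the list alone), Gsn at 1.54 ± 0.22 and the matrix protein gene Dpt at 1.37 ± 0.23 (adjusted p = 0.0168, adjusted p = 0.767 with an estimated correlation); this list lost its call without control library 2 or mutant library 1, with adjusted p of 0.158 and 0.0828.

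The thermogenic programme had 9 of 31 members called lower, 3 higher and 19 not called, with 12 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.00123, adjusted p = 0.629 with an estimated correlation). Log2 fold changes were -2.03 ± 0.26 (SE) for Slc27a2 and -2.40 ± 0.41 for Cpn2. Elovl3, a fatty acid elongase of the same list, rose by 1.61 ± 0.27, and Adrb3, the beta-3 adrenergic receptor, by 1.41 ± 0.27 (adjusted p = 0.0519 without control library 3). Of the always named genes, Ppargc1a (0.30 ± 0.33), Dio2 (0.04 ± 0.44), Prdm16 (-0.17 ± 0.28), Cidea (-0.84 ± 0.26), Fgf21 (2.90 ± 1.05), Pparg (-0.05 ± 0.19) and Adipoq (0.60 ± 0.16) were not called. The nuclear receptor genes Esrrg and Esrra were lower by log2 fold changes of -1.06 ± 0.18 and -0.69 ± 0.15. Ucp1 was not called without control library 2 or 3 or mutant library 2 or 3, with adjusted p between 0.0654 and 0.0844. With only the groups compared Ucp1 and Cpn2 were not called (0.0747 and 0.087), and Esrra was not called when any 1 library other than control library 1 was left out (0.0601 to 0.0851).

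Respiratory chain lists were lower as groups, though few single members passed. The list of mitochondrially encoded transcripts had 0 members among the measured genes, so these lists cover nuclear-encoded subunits only. Complex I had 1 of 37 members called lower and 36 not called (0 adjusted over the list alone), with a median log2 fold change of -0.67 (adjusted p = 1.66e-10, adjusted p = 0.758 with an estimated correlation). Complexes II and III had 0 of 14 called (2 lower adjusted over the list alone; median -0.68, adjusted p = 7.41e-05, adjusted p = 0.758 with an estimated correlation). Complex IV had 1 of 16 lower (1 adjusted over the list alone; median -0.75, adjusted p = 0.00021, adjusted p = 0.758 with an estimated correlation) and ATP synthase 1 of 17 lower (1 adjusted over the list alone; median -0.54, adjusted p = 0.00254, adjusted p = 0.758 with an estimated correlation). Mitochondrial ribosomal protein genes had 1 of 76 lower (0 adjusted over the list alone; median -0.29, adjusted p = 1.23e-06, adjusted p = 0.767 with an estimated correlation). The TCA cycle had 3 of 24 lower and 2 higher (9 and 2 adjusted over the list alone; adjusted p = 0.000751, adjusted p = 0.758 with an estimated correlation), with Pcx, pyruvate carboxylase, at 1.49 ± 0.19 (SE). Mitochondrial fatty acid oxidation had 5 of 25 lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 7.41e-05, adjusted p = 0.742 with an estimated correlation). Without the 4 muscle-rich libraries 1 control library is left at room temperature, and the spread comes from the other groups. The median log2 fold change over the 84 subunits of the respiratory chain and ATP synthase was then -0.332, against -0.683 with all libraries. Complexes II and III, complex IV, ATP synthase, mitochondrial ribosomal proteins and the TCA cycle were not called as lists in that fit (adjusted p from 0.0713 to 0.807), which does not tell muscle from the loss of controls.

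Skeletal muscle transcripts varied between libraries, from 0.00982% of counts in mutant room temperature library 2 to 3.10% in control room temperature library 1. They took 2.20% in control library 3 and 2.03% in mutant library 3 at room temperature. Of the 26 muscle genes 0 were called between genotypes at room temperature in edgeR, and 0 adjusted over the list alone (median log2 fold change -1.32, camera adjusted p = 0.204), while 2 of 18 calcium cycling genes (adjusted p = 0.104) and 2 of 8 creatine cycle genes were lower and 1 higher (adjusted p = 0.276), with the same counts adjusted over the list alone. The muscle list was called lower without control library 2 (adjusted p = 5.34e-06) or mutant library 3 (0.0333), as was calcium cycling (0.017 and 0.0105). Transcripts of the eye lens were among the largest falls. Cryaa, the alpha-A crystallin gene, was 132 ± 119 CPM (SD, n = 3) in controls and 0.333 ± 0.0906 CPM in mutants. Mip, a lens water channel gene, was at 0 counts in all 3 mutant libraries and at least 273-fold lower there against 3 counts over the group. Of 23 lens genes tested, 21 were called lower at room temperature and 0 in the cold. The lens set was not among the fixed lists and was added after the data were seen, so the 21 are not an independent test. All 3 room temperature control libraries and all 6 cold libraries held them.

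**Figure D2:**
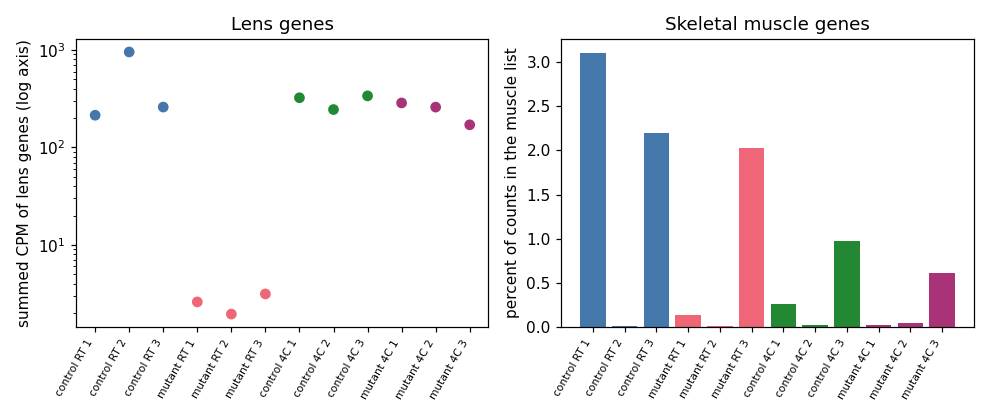
Summed CPM of the lens genes on a log axis (left) and percent of counts in the muscle list (right) for each of the 12 libraries, coloured by group. The 3 mutant room temperature libraries hold between 1.95 and 3.13 CPM of lens transcripts and the other 9 between 171 and 955 CPM.

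In the cold, fewer genes separated the genotypes, and few gene groups had called members. Of 15265 genes 171 were called, 111 higher and 60 lower in libraries labelled mutant. Hgd, homogentisate dioxygenase, was 4.05 ± 1.17 CPM (SD, n = 3) in mutants, with 383 counts over the group (edgeR adjusted p = 0.00855). In controls Hgd was under the floor of detection on average, with 4 counts in 1 library. Rasef was higher by a log2 fold change of 4.62 ± 0.49 (SE) and Serpina1a, an alpha-1-antitrypsin gene, by 4.03 ± 0.50. Slc29a1, a nucleoside transporter gene, had a log2 fold change of -2.14 ± 0.23, Vil1, which encodes villin, -2.32 ± 0.26 and Btc, which encodes betacellulin, -2.63 ± 0.31. The count was 59, 44 and 28 without control cold library 1, 2 or 3, and 64 and 97 without mutant cold library 1 or 3. It was 18 without the 4 muscle-rich libraries, of which 1 is cold control library 3.

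Peroxisomal fatty acid oxidation had 3 of 20 called higher in the cold and 9 adjusted over the list alone (camera adjusted p = 4.37e-06, adjusted p = 0.318 with an estimated correlation). Lipolysis and lipid uptake had 1 of 18 higher (4 adjusted over the list alone; adjusted p = 0.00123, adjusted p = 0.234 with an estimated correlation), general adipocyte genes 1 of 24 (5 adjusted over the list alone; adjusted p = 0.00238, adjusted p = 0.677 with an estimated correlation) and white-fat-enriched genes 1 of 16 (1 adjusted over the list alone; adjusted p = 0.00123, adjusted p = 0.677 with an estimated correlation). Proliferation genes had 0 of 28 called (0 adjusted over the list alone), with a median log2 fold change of 0.55 (adjusted p = 6.41e-08, adjusted p = 0.677 with an estimated correlation). Interferon-stimulated genes had 1 of 23 lower (1 adjusted over the list alone; median -0.32, adjusted p = 0.000918, adjusted p = 0.677 with an estimated correlation). Macrophage genes had 0 of 20 called (0 adjusted over the list alone; median -0.63, adjusted p = 0.042, adjusted p = 0.804 with an estimated correlation), and the list was not called without control cold library 1 or mutant cold library 1 or 2 (adjusted p 0.765, 0.112 and 0.0727).

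Thermogenic genes had 0 of 31 called in the cold, and 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.913, median log2 fold change -0.08, mean 0.10, test direction higher), and Ucp1 was 9505 ± 3169 CPM (SD, n = 3) in mutants and 11935 ± 378 CPM in controls. Lipogenic genes had 1 of 22 called higher (1 adjusted over the list alone; adjusted p = 0.806) and cholesterol synthesis genes 0 of 22 (0 adjusted over the list alone; adjusted p = 0.361). The respiratory lists had 0 members called over all genes or adjusted over the list alone. Their medians were -0.37 for complex I (adjusted p = 1.64e-06), -0.39 for complexes II and III (0.00118), -0.47 for complex IV (0.000895) and -0.42 for ATP synthase (0.0008), each with adjusted p = 0.758 with an estimated correlation. Mitochondrial ribosomal proteins (0 of 76) and the TCA cycle (0 of 24), each with 0 adjusted over the list alone, were called as lists too (adjusted p 0.000751 and 0.00123, adjusted p = 0.866 and 0.758 with an estimated correlation). Those calls rested on mutant cold library 3. Without it the adjusted p was 0.293, 0.332, 0.299 and 0.223 for the respiratory lists and 0.253 for the TCA cycle, and the ribosomal list was higher, at 0.0489. That library also held 79.3 CPM of Krt8 and 18.9 CPM of Epcam, epithelial genes at most 9.9 and 3.37 CPM in the other 11.

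Across 15265 genes, genotype fold changes at the 2 temperatures, which share no library, had Pearson's r = 0.299, Spearman's rho = 0.295 and a slope of 0.265; genes are not independent replicates. Of the 171 genes called in the cold, 149 (87.1%) had the same sign at room temperature. Called higher at both were 47 genes, where independent lists would share 4.35, and called lower at both were 30, where they would share 1.39. Opposite calls numbered 2. Without control cold library 3 r was 0.151, and without the 4 muscle-rich libraries it was 0.0829.

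**Figure D3:**
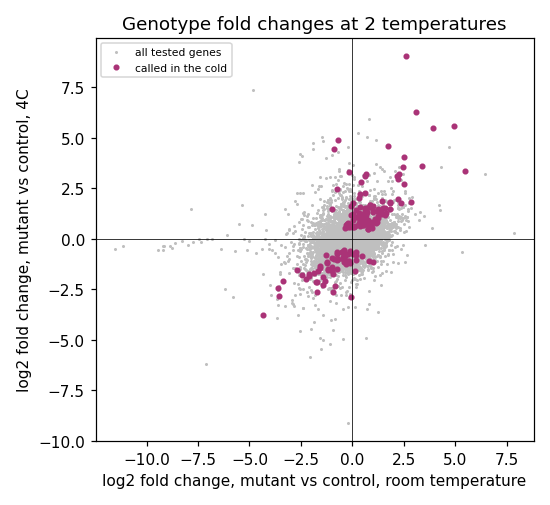
Log2 fold change of mutant against control at room temperature (horizontal) and at 4 degrees (vertical) for each of 15265 tested genes (grey points), with the 171 genes called in the cold marked. Of these, 149 lie in the quadrants of equal sign.

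In controls, cold raised members of the glycolysis, lipogenesis and cholesterol synthesis lists. Elovl3 rose from 20.5 ± 6.43 to 572 ± 58 CPM (SD, n = 3; log2 fold change 4.80 ± 0.30 SE, adjusted p = 3.32e-05). Bmp8b, a secreted factor of brown fat, rose from 0.751 ± 0.974 to 37.4 ± 5.34 CPM (5.59 ± 0.86, adjusted p = 0.00727). Ucp1 rose from 4454 to 11935 CPM (1.42 ± 0.39, adjusted p = 0.0492); it lost its call without any 1 of the 6 libraries (adjusted p from 0.0729 to 0.132) and with the replicate block (0.0722). In total 1010 genes were called, 658 higher and 352 lower (1072 and 879 in DESeq2). The count was 616 and 396 without control room temperature library 2 or 3, and 414, 324 and 313 without cold library 1, 2 or 3. Without the 4 muscle-rich libraries, which leaves 1 room temperature control, it was 13.

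Cholesterol synthesis had 15 of 22 members called higher in cold controls and 16 adjusted over the list alone (camera adjusted p = 1.91e-13, adjusted p = 0.234 with an estimated correlation), with Fdps at 1.96 ± 0.23 (SE). Lipogenic genes had 12 of 22 higher and 19 adjusted over the list alone (adjusted p = 1.28e-11, adjusted p = 0.402 with an estimated correlation). Glucose uptake and glycolysis had 14 of 22 higher and 1 lower, 15 and 1 adjusted over the list alone (adjusted p = 2.61e-09, adjusted p = 0.275 with an estimated correlation), with Pfkp at 1.94 ± 0.20 and Gpi1 at 1.51 ± 0.22. The thermogenic programme had 9 of 31 higher, and 13 higher and 2 lower adjusted over the list alone (adjusted p = 4.37e-06, adjusted p = 0.318 with an estimated correlation). Mitochondrial ribosomal proteins had 10 of 76 higher (16 adjusted over the list alone; adjusted p = 3.07e-09, adjusted p = 0.758 with an estimated correlation) and mitochondrial fatty acid oxidation 3 of 25 (6 adjusted over the list alone; adjusted p = 0.000213, adjusted p = 0.758 with an estimated correlation), led by Acsl5 at 2.67 ± 0.25. Alpl, an alkaline phosphatase gene of the creatine cycle list, rose by 1.76 ± 0.12. Log2 fold changes were -4.16 ± 0.54 for the nuclear receptor gene Nr4a3, -2.83 ± 0.46 for the glucocorticoid-responsive gene Fkbp5 and -1.91 ± 0.30 for the transcription factor gene Foxo1.

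The TCA cycle (0 of 24 called, 4 higher adjusted over the list alone), complex I (0 of 37) and complexes II and III (0 of 14), the last 2 with 0 adjusted over the list alone, were higher as lists in cold controls. Their adjusted p was 0.000109, 0.00123 and 0.00238, and adjusted p = 0.758, 0.843 and 0.758 with an estimated correlation. Complex IV (0 of 16) and ATP synthase (0 of 17), also with 0 adjusted over the list alone, were not called as lists (adjusted p = 0.0646 and 0.0514). Complex IV was called without control room temperature library 3 or cold library 2 or 3 (camera adjusted p 0.0186, 0.0447 and 0.0483). ATP synthase was called without room temperature library 1 or 3 or cold library 2 (0.0499, 0.0156 and 0.0345). Transcript length was correlated across genes with each gene's deviation from its mean over all libraries, in log2(CPM + 1). Spearman's correlation was -0.238, -0.224 and -0.141 in the cold controls. In room temperature controls it was -0.0745, 0.197 and -0.0119. Results for these lists with the length trend removed are not given here, so the part of length in their rise is left open. Peroxisomal fatty acid oxidation had 2 of 20 higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.00109, adjusted p = 0.621 with an estimated correlation). Amino acid stress response genes had 4 of 21 higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0269, adjusted p = 0.642 with an estimated correlation). Endothelial genes had 3 of 17 higher (7 adjusted over the list alone; adjusted p = 0.0329, adjusted p = 0.758 with an estimated correlation). White-fat-enriched genes (1 of 16 lower, 3 adjusted over the list alone), fibroblast genes (1 of 20 lower, and 3 lower and 1 higher adjusted over the list alone) and the unfolded protein response (0 of 17, and 2 higher and 2 lower adjusted over the list alone) were lower as lists, with adjusted p of 0.0144, 0.0252 and 0.0412, and adjusted p = 0.758, 0.767 and 0.758 with an estimated correlation. Leaving out 1 library ended the calls of the last 5 lists in at least 1 fit, with camera adjusted p up to 0.0731, 0.171, 0.114, 0.406 and 0.182. The skeletal muscle list was called lower without control room temperature library 2 (4.214e-05). Macrophage genes were called higher as a list without room temperature library 1 or cold library 2 or 3 (0.008843, 0.03771 and 0.009463). Extracellular matrix, proliferation, clock and sex-linked lists also gained a call in at least 1 fit.

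In libraries labelled mutant, cold called 2663 genes, 1531 higher and 1132 lower. The comparison rests on the 3 mutant room temperature libraries with lens transcripts near the floor, and 19 of 23 lens genes were among those called higher. Ucp1 was 9505 ± 3169 CPM (SD, n = 3) in the cold and 1308 ± 659 CPM at room temperature (log2 fold change 2.86 ± 0.41 SE, adjusted p = 0.000793). Elovl3 rose from 62.8 ± 18.4 to 1071 ± 130 CPM (4.09 ± 0.29) and Esrra and Esrrg by 1.21 ± 0.15 and 1.03 ± 0.18. Bmp8b had 2 counts over the room temperature group and 3490 in the cold, a 1777-fold ratio with a counting interval of 492 to 14680. Ckb, cytosolic creatine kinase, rose by 3.73 ± 0.38. The count was 1547 and 1734 without mutant room temperature library 2 or 3, 1466 and 1719 without mutant cold library 1 or 2, and 1218 without the 4 muscle-rich libraries.

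The thermogenic programme had 20 of 31 members called higher in cold mutants and 22 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.66e-10, adjusted p = 0.234 with an estimated correlation). Mitochondrial fatty acid oxidation had 14 of 25 higher (16 higher and 1 lower adjusted over the list alone; adjusted p = 1.07e-07, adjusted p = 0.677 with an estimated correlation), with Slc25a20, the carnitine carrier, at 1.36 ± 0.19 (SE). Complex I had 9 of 37 higher (12 adjusted over the list alone; adjusted p = 5.19e-06, adjusted p = 0.758 with an estimated correlation), complexes II and III 7 of 14 (8 adjusted over the list alone; adjusted p = 0.000729, adjusted p = 0.758 with an estimated correlation) and mitochondrial ribosomal proteins 27 of 76 (36 adjusted over the list alone; adjusted p = 7.47e-10, adjusted p = 0.758 with an estimated correlation). Complex IV had 2 of 16 higher (2 adjusted over the list alone; adjusted p = 0.01955, adjusted p = 0.791 with an estimated correlation) and was not called as a list without mutant room temperature library 3 or mutant cold library 1 or 2 (adjusted p 0.101, 0.11 and 0.261). ATP synthase had 3 of 17 higher (3 adjusted over the list alone) and was not called as a list (adjusted p = 0.0889), but was without mutant room temperature library 1 or mutant cold library 3 (0.0291 and 8.94e-06). Mutant cold library 3 did not share the rise of complexes I to IV, mitochondrial ribosomal proteins or the TCA cycle. Its mean log2(CPM + 1) was 7.462 for complex I and 7.222 for complex IV, under all 3 mutant room temperature libraries (at least 7.495 and 7.363). It was 8.754 for complexes II and III, 5.508 for mitochondrial ribosomal proteins and 9.284 for the TCA cycle, each between the lowest and highest of those 3. Glycolysis had 10 of 22 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 7.98e-05, adjusted p = 0.599 with an estimated correlation), with Hk1 at 1.73 ± 0.28. Proliferation genes had 11 of 28 higher and 20 adjusted over the list alone (adjusted p = 9.09e-09, adjusted p = 0.677 with an estimated correlation), with Rrm2, a ribonucleotide reductase gene, at 2.16 ± 0.39. White-fat-enriched genes had 6 of 16 lower and 1 higher (9 and 1 adjusted over the list alone; adjusted p = 0.00134, adjusted p = 0.679 with an estimated correlation), with Nnat at -3.63 ± 0.39. Fibroblast genes had 5 of 20 lower (6 adjusted over the list alone; adjusted p = 0.000822, adjusted p = 0.758 with an estimated correlation), among them Dpt at -1.75 ± 0.23 and Gsn at -1.68 ± 0.22. Adipoq, the adiponectin gene, had -1.31 ± 0.17 and Cfd, which encodes adipsin, -1.89 ± 0.35. Cholesterol synthesis had 5 of 22 higher and 3 lower (5 and 3 adjusted over the list alone; adjusted p = 0.829) and lipogenesis 1 of 22 higher and 4 lower (1 and 5 adjusted over the list alone; adjusted p = 0.659). The TCA cycle had 10 of 24 higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 0.000485, adjusted p = 0.758 with an estimated correlation). Immediate early genes had 5 of 20 lower (7 adjusted over the list alone; adjusted p = 0.01955, adjusted p = 0.742 with an estimated correlation). Peroxisomal fatty acid oxidation had 7 of 20 higher and 3 lower (8 and 4 adjusted over the list alone; adjusted p = 0.0253, and 0.053 without mutant cold library 1), endothelial genes 4 of 17 higher (4 adjusted over the list alone; 0.0172, and 0.1175 without mutant room temperature library 3), both with adjusted p = 0.742 with an estimated correlation. Neighbours of the Ebf2 gene had 2 of 8 higher (2 adjusted over the list alone; adjusted p = 0.0494, adjusted p = 0.53 with an estimated correlation), not called without mutant room temperature library 1 or mutant cold library 2 or 3 (0.0951, 0.0516 and 0.108).

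**Figure D4:**
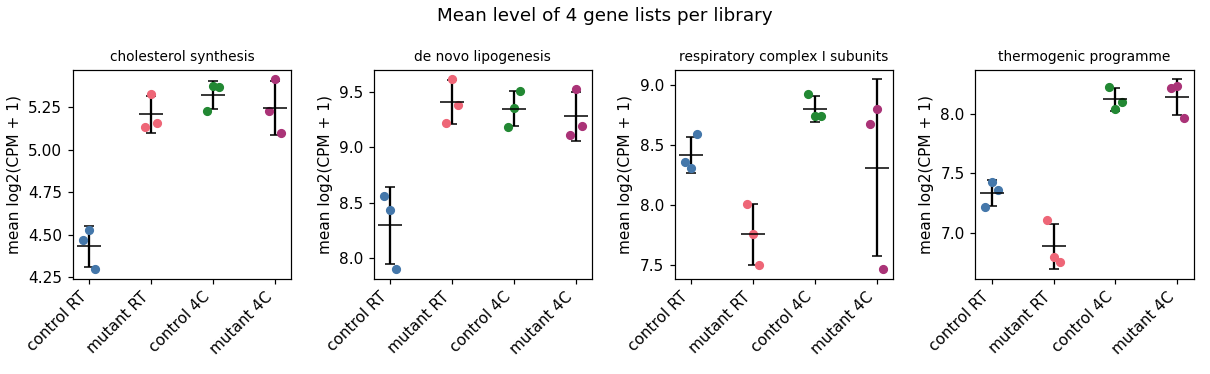
Mean log2(CPM + 1) over the members of 4 gene lists in each library (points), with the mean and SD of each group of 3 (bars). Cholesterol synthesis and lipogenesis are high in mutants at room temperature and in both cold groups, while complex I and the thermogenic programme are low in mutants at room temperature, and mutant cold library 3 lies at 7.46 for complex I.

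Most genes called with cold in both genotypes took the same direction. Called higher in both were 444 genes, where independent lists would share 66, called lower in both 172, where they would share 26.1, and 7 were called in opposite directions. For 3792 genes past the threshold for the mean cold effect, changes were taken in the direction of that mean. Their median was 0.54 in controls and 0.73 in mutants on the log2 scale. Of these genes 67.4% changed more in mutants, and 53 passed the interaction test. Genes are not independent replicates, and the mutant changes rest on the room temperature libraries with lens transcripts near the floor.

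The genotype by temperature interaction called 73 genes, 45 positive and 28 negative, where positive means a higher cold response in libraries labelled mutant. The balance of signs depended on the method, with 222 and 214 in DESeq2, and 478 positive and 643 negative in limma-voom with quality weights. Cholesterol synthesis and lipogenesis were negative as lists, with few members called. Cholesterol synthesis had 3 of 22 called negative and 16 adjusted over the list alone (camera adjusted p = 3.75e-15, adjusted p = 0.234 with an estimated correlation). Lipogenesis had 2 of 22 negative and 12 adjusted over the list alone (adjusted p = 1.91e-13, adjusted p = 0.329 with an estimated correlation). Insig1 had an interaction of -1.72 ± 0.22 (SE, adjusted p = 0.00763), and Slc25a1 -2.48 ± 0.34 (0.0103). Sik1, a kinase gene, had -1.86 ± 0.25 and Wscd2 -3.11 ± 0.35. Thermogenic genes had 0 of 31 called, and 2 positive and 1 negative adjusted over the list alone (adjusted p = 0.00109 as a list, median 0.64, adjusted p = 0.599 with an estimated correlation), and Ucp1 had 1.44 ± 0.54 (adjusted p = 0.306). Of the 45 positive calls 14 were lens genes, led by Cryba1 at 8.77 ± 0.82.

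With the replicate block the interaction called 34 genes, 33 of them among the 73. Without the 4 muscle-rich libraries, which leaves 1 control library at room temperature, fewer genes were called than in the main fit, and nearly all were positive. Leaving out 1 library gave 204 without control room temperature library 1 and 35 and 29 without 2 and 3. It gave 33, 31 and 33 without mutant room temperature library 1, 2 and 3, 25, 13 and 14 without control cold library 1, 2 and 3, and 13 without mutant cold library 1. Without control cold library 3 or mutant cold library 1 Slc25a1 was not called (adjusted p 0.0528 and 0.0586).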

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

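The interaction values below come from a comparison fixed before the data were examined, while the tests on lens transcripts, respiratory subunits and Ebf2 were chosen after the results were seen. Results whose cold response differed between genotypes by the interaction test are given first.

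The interaction called 73 genes in edgeR. Negative values, for a smaller rise or larger fall with cold in libraries labelled mutant, were -1.76 for Aacs, -1.36 for Fam107b, -1.72 for Insig1, -1.95 for Irf7, -1.32 for Mcam, -1.81 for Nsdhl, -1.86 for Sik1, -2.48 for Slc25a1 and -3.11 for Wscd2 (log2). Positive values were 0.89 for Alpl, 2.35 for Als2cr12, 2.58 for Arhgef37, 8.43 for Cryaa, 8.77 for Cryba1, 7.18 for Cryba4, 8.68 for Crygs, 3.70 for Fam131c, 2.58 for Kng2, 3.47 for Lamb3, 1.19 for Ldhb, 2.57 for Nfil3 and 1.72 for P2ry1. With the replicate block Aacs, Alpl, Kng2, Ldhb, Mcam and Nfil3 were not called. Leaving out 1 library ended the call of Aacs, Alpl, Als2cr12, Fam107b, Irf7, Kng2, Ldhb, Mcam, Nfil3, Nsdhl, P2ry1 or Slc25a1 in at least 1 fit.

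The interaction called 11 lists, with camera adjusted p of 3.755e-15 for cholesterol synthesis, 1.915e-13 for lipogenesis, 7.021e-06 for proliferation, 0.0007291 for general adipocyte identity and 0.001092 for the thermogenic programme. The others were 0.007617 for macrophages, 0.01441 for interferon-stimulated genes, 0.01458 for mitochondrial fatty acid oxidation, 0.02532 for immediate early genes, 0.03595 for Schwann cells and nerve and 0.04199 for fibroblasts and preadipocytes. None kept its call with an estimated correlation, where the smallest adjusted p was 0.234. Leaving out 1 library ended the last 6 calls in at least 1 fit, with adjusted p up to 0.215, 0.0802, 0.294, 0.1793, 0.1784 and 0.322. It also added calls. Without mutant cold library 3, which stood apart, the interaction called complex I (9.264e-17), mitochondrial ribosomal proteins (2.92e-13), complexes II and III (7.792e-07), complex IV (9.905e-06), the TCA cycle (0.0001938) and ATP synthase (0.001082) as positive. It called extracellular matrix (0.0001203), white-fat-enriched genes (0.009182) and mural cells (0.03013) as negative in that fit. In other fits complex I (smallest 0.004202), mitochondrial ribosomal proteins (0.005185), white-fat-enriched genes (0.02488), glycolysis (0.01652), red blood cells (0.003056) and the sex-linked list (0.02898) were called.

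Of 100 drawn splits of the genotype labels within each temperature, 5 gave at least 73 genes, the real one included, so chance was not excluded; the highest other gave 1237. That split exchanged the 2 genotypes in the cold, which turns the interaction into a test of the summed genotype effect. All 4 of the other splits that gave as many were among 19 that keep the genotype groups of at least 1 temperature whole and so hold the difference between the labelled genotypes there. The 80 splits that mix the genotypes at both temperatures gave at most 1 gene. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05, and in each case 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 952 and 29 for genotype at room temperature, 171 and 1 for genotype in the cold, 1010 and 0 for cold in controls and 2663 and 306 for cold in mutants.

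Lens transcripts were present in 9 libraries and near the floor in the 3 mutant room temperature libraries. A lowering by the genotype itself is argued against, since the median log2 fold change of 23 lens genes in the cold was -0.376 with quartiles of -0.547 and -0.183. Over the 9 libraries, 15 lens genes kept their ratios, with a median SD of 0.234 against 0.677 for the lens mean (log2). That contrast rests largely on control room temperature library 2, without which the values were 0.223 and 0.355. Both are consistent with a single source of lens RNA or reads, though genes regulated together could give the same, and Cryaa ran from 40.6 to 269 CPM there. Whether the 3 mutant libraries, all 3 below the other 9, were handled or sequenced apart cannot be told apart from their group. This would bear on every comparison that uses them, cold in mutants and the interaction included. A biological effect limited to mutants at room temperature stays open and untested.

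Respiratory chain and ATP synthase subunits were lower in mutants at room temperature, with a median log2 fold change of -0.683 and 83 of 84 genes below 0. Transcript length as the whole cause is argued against: with each library's length trend removed the median was -0.599, and 0 of 10000 random lists matched on length and level were as low (lowest -0.25). Muscle carry-over stays open, since the median was -0.727 with a muscle covariate but -0.332 without the muscle-rich libraries, a fit that leaves 1 room temperature control and was set beside the first after both values were seen. Single libraries go both ways. Mutant library 3, with 2.03% of counts in the muscle list, had the lowest mean deviation of the 6 room temperature libraries (-0.783). Control library 2, with 0.0122%, lay above all 3 mutants (-0.139), but below the muscle-rich control libraries 1 and 3 (0.128 and 0.31). In mean log2(CPM + 1), control library 2 lay below mutant library 1 for complex IV (7.929 against 8.001) and ATP synthase (8.235 against 8.348). In the mean over the 84 subunits all 3 mutant libraries lay below every control. Separate handling of these 3 libraries cannot be told apart from the genotype, because the lens transcripts part the same 3 libraries from the rest. An effect of the genotype remains a hypothesis.

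Ebf2 was not lower in mutants at room temperature. Of the genes called in the cold, 87.13% had the same sign there. A swap of the room temperature genotype labels would put that share under 50% if genotype effects agree between temperatures. Pearson's r over all genes was 0.299, but it rests on the same labels and cannot show that premise. The share therefore does not decide whether labels were swapped. Kng1, higher in mutants in the cold, was under the floor on average in mutants at room temperature. Nothing here shows that Kng1 should be raised at both temperatures, so this does not decide on the label there. Reads from remaining exons or from cells without Cre could give a log2 fold change of 0.0576 over the whole gene, and counts per exon were not analysed here, so this cannot be told apart from an intact gene.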

How the results depend on the processing

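The muscle covariate, the length correction (with and without the block) and the set without muscle-rich libraries were chosen after the data were seen. Genotype counts at room temperature (952) became 1651 in DESeq2 (945 shared), 2844 in limma-voom with quality weights, 552 with only the groups compared, 527 with an absolute log2 fold change of at least 1, 129 without muscle-rich libraries and 395 to 1152 leaving out 1 library. In the cold (171) they became 717 (all 171 shared), 1119, 102, 113, 18 and 28 to 133. For cold in controls (1010) DESeq2 gave 1951, limma-voom 3402, the fold minimum 408 and the set without muscle-rich libraries 13, with 313 to 971 leaving out 1 library. For cold in mutants (2663) limma-voom gave 5075, the groups compared 1633, the fold minimum 1125 and the reduced set 1218, with 1466 to 3630. The interaction (73) became 436 in DESeq2, 1121 in limma-voom, 48 without robust fitting, 34 with the replicate block, 26 without muscle-rich libraries and 13 to 204. The share of higher calls moved from 65.2% to 55% for cold in controls and from 61.6% to 50.9% for the interaction in DESeq2. With the replicate block the other counts were 873, 125, 1014 and 2671. In no comparison did every sample correlate best with its own number.

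Ebf2 in the cold passed in limma-voom (-0.75) and with the block and length trend removed (-0.91), and ran from -0.90 to -0.70 leaving out 1 library; at room temperature it ran from -0.18 to 0.33. List calls (70) were 0 with an estimated correlation, 28 with fry and 68 to 83 leaving out 1 library. The genotype correlation fell to 0.083 without muscle-rich libraries, was 0.368 with mean CPM of at least 1 and ran from 0.151 to 0.307 leaving out 1 library, and the excess cold response ran from 0.13 to 0.27. Directions turned for 7 list results, counting only lists called in the main fit or the alternative. These were proliferation at room temperature (adjusted p 0.0186) and fibroblasts in cold controls (0.812) without muscle-rich libraries, mitochondrial ribosomal proteins in the cold with quality weights (0.591) and, without mutant cold library 3, the same list (0.0489), extracellular matrix (0.00712) and fibroblasts (0.039). The muscle list turned in the interaction without control room temperature library 2 (0.017). Leaving out 1 library, adjusted p ran from 5.18e-09 to 0.0489 for the ribosomal list, 0.000898 to 0.356 for matrix, 0.039 to 0.729 for fibroblasts and 0.017 to 0.957 for muscle. The causes were not tested. No named gene reversed among those called in the main fit or the alternative. A change of sign in a gene called in neither, such as Ebf2 at room temperature, was not counted. Of 278 calls of named genes 144 held in every fit leaving out 1 library, as did 46 of 70 list calls. Calls of named genes were lost for 30 with the replicate block, 6 with RLE, 0 of 277 in DESeq2, 56 of 254 with only the groups compared and 170 without muscle-rich libraries. Only-the-groups fits do not exist for the interaction. Depth limits genes near 0.1 CPM.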

Other observations

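The genes in this part were chosen after their values were seen unless a list names them. Neighbours of the Adipoq gene, listed because a transgene carrying that region could bring them along, included Kng1, a kininogen gene. Kng1 was 6.02 ± 2.59 CPM (SD, n = 3) in cold mutants and 0.196 ± 0.102 CPM in cold controls, and under the floor of detection on average in mutants at room temperature (0.0679 ± 0.118 CPM). Its call in the cold (log2 fold change 4.90 ± 0.88 SE, edgeR adjusted p = 0.0266) was lost without any 1 of the 3 control cold libraries or without mutant cold library 1, with adjusted p between 0.0852 and 0.15. Kng2 was 9.45 ± 3.86 CPM in mutants and 68.4 ± 33.2 CPM in controls at room temperature, and 146 ± 26.5 and 177 ± 19.2 CPM in the cold. The list was not called in either genotype comparison (camera adjusted p = 0.922 and 0.217), and at room temperature its median (-0.18) and test direction (higher) differed in sign.

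Clock genes differed with cold in mutants, where 2 of 18 were higher and 9 lower, 5 and 11 adjusted over the list alone (camera adjusted p = 0.0402, adjusted p = 0.742 with an estimated correlation). Arntl, a core clock activator, was 11.4 ± 5.99 CPM (SD, n = 3) in the cold and 1.57 ± 0.694 CPM at room temperature, and Dbp fell by 2.06 on the log2 scale (adjusted p from 0.0544 to 0.073 without mutant room temperature library 2 or mutant cold library 1 or 3). The list was not called without mutant room temperature library 2 or mutant cold library 1 (adjusted p 0.058 and 0.0988). The time of tissue collection is not given in the sources used here.

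Mutant cold library 3 stood apart from the other 11 libraries. Its keratin genes Krt18 and Krt19 were at 66.4 and 54.6 CPM, at most 2.33 and 5.65 CPM elsewhere, and Csn3, a milk casein gene, was at 14.4 CPM, against 2.997 and 1.81 CPM in mutant cold libraries 1 and 2 and at most 0.302 CPM in the other 9. Spearman's correlation of transcript length with the deviation of each gene from its mean over the 12 libraries was 0.31 in this library, the highest of the 12. The mean deviation of ribosomal protein genes was -0.541 there on the log2 scale.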
